A study of Rattus norvegicus with 18 samples.

How the data were processed

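Whole hippocampus of 18 adult male rats, 6 each of bHR, bIR and bLR, was sequenced as stranded polyA libraries in paired-end runs, per the labels' protocols, with 1 library per rat. Per the labels' protocols and the submitters' processing notes, the authors aligned reads with Subread to Rnor_6.0, counted them with featureCounts on Ensembl genes, kept genes with at least 10 counts in at least 4 samples and an official symbol, and deposited log2 values from voom in limma (R 3.2.2). The deposited log2 values are log2 FPM (fragments scaled for library depth) with an offset of 0.5 reads. Versions of Subread, featureCounts and limma are not given in the sources used here, nor is the method behind the library scaling.

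The lowest value of each column was taken as 0 reads. With 1 constant per column, 100% of the 376362 values came within 0.02 of a whole number of reads (largest distance 2.56e-08). The constants differed from the read totals by factors of 0.974 to 1.04, as a scaling factor per library would give. Totals ranged from 31.1 to 66.6 M reads, so a gene at 1 FPM rests on about as many reads as the library holds in M. In the recovered reads, 1258 of the 20909 genes had 10 or more reads in fewer than 4 libraries, so the stated filter does not describe every gene. A placeholder symbol (LOC or RGD) is carried by 5804 genes. No symbol of a mitochondrially encoded gene was measured. Reads shared between near-identical copies were handled by the authors' counting, which is not described in further detail. Gene symbols were matched, for neighbouring genes only, to a table of the GRCr8 assembly. That assembly differs from the one the values were made on, so no coordinates are given.

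Groups came from the sample titles, and replicate numbers are the rats' own numbers, with none shared between lines. Tests were made with limma 3.58.1 in R 4.3.3 on the deposited log2 values: a model of 3 line means over all 18 rats, contrasts between lines and of bIR with the mean of bHR and bLR, empirical Bayes with a trend on mean expression, two-sided, Benjamini-Hochberg over all genes and an adjusted p under 0.05. No filter was added. A further model had 1 common slope on percent time in the open arms beside the line means. Behavioural scores were compared by exact two-sided permutation of the difference in means, adjusted over 15 tests. Gene lists, 34 in all, were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Lists with at least 3 measured members, apart from the list of candidate genes, gave 32 tests with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over lists within a contrast. With fry, whose test asks whether the members move one way on balance, 0 lists passed in each of the 4 contrasts. By its mixed test, which asks whether members change in either direction, 7 lists passed between bHR and bLR, 0 between bHR and bIR, and the immediate early genes alone between bLR and bIR (adjusted p = 0.0437) and between bIR and the mean of the lines (adjusted p = 0.0346).

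Named genes between bHR and bLR were the 12 with the largest positive and the 12 with the largest negative log2 difference among genes with an adjusted p under 0.05, a mean log2 value of at least 0 and no overlap between the lines. The other contrasts took 6 each way, lists up to 4 members of smallest adjusted p, and candidate genes any measured member. Placeholder symbols were passed over. The exceptions, named after their values were seen, are stated where they occur.

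The fits were tested on simulated reads for the 20909 genes with some genes changed between bHR and bLR. Changes of 0.5 on the log2 scale were recovered in 59.7% of 67 genes, of 1 in 92.5% of 67 and of 2 in 100% of 66, and 6 of 174 calls were false. With no gene changed, 0 genes were called in each contrast. Reads were simulated separately for each gene, so variation shared between genes was absent. The changed genes all had a mean log2 value of at least 0, as 18 of the 93 genes called between bHR and bLR did not. These rates therefore need not hold for the real libraries. In these simulations bIR lay at the log2 midpoint, and 0 genes were called off the midpoint.

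Alternatives covered filters on low values, median centring, scaling by a trimmed mean of log ratios (30% of log ratios and 5% of levels trimmed), quantile normalization, other variance models, array weights, a prior of 2 reads, voom weights, depth as a covariate, only the 12 rats compared and leaving out each rat. Chosen after seeing the data were the mean of the choroid plexus markers as a covariate, leaving out the 4 libraries with Ttr above 11, the exact permutation of list means, and the carrying over of some settings to the lists and the bIR position.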

Results

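Gene expression in the whole hippocampus was measured by RNA sequencing in 18 adult male rats, 6 from each of 3 groups. Bred High Responder rats (bHR) and bred Low Responder rats (bLR) come from selective breeding on locomotor activity in an unfamiliar environment, here in generation 37. Bred Intermediate Responder rats (bIR) are a cross of bHR with bLR. Each rat gave 1 library, so replicates are separate animals, named below by their titles (HR, IR or LR with the rat's number). The labels give no batch, lane or litter, so whether rats of a line shared any of these is not known. Levels are given in FPM, fragments scaled for library depth. Folds are back-transformed differences of mean log2 values, so they need not equal the ratio of the mean FPM levels. Read totals recovered from the deposited values ranged from 31.1 to 66.6 M reads per rat, with means of 39.2 M in bHR, 45.5 M in bIR and 48.7 M in bLR. Values were available for 20909 genes, and correlations between libraries ranged from 0.962 to 0.981. The bHR and bLR rats were sacrificed at postnatal ages P160 to P167 and the bIR rats at P126 to P134, so any difference of bIR from the other lines is also a difference in age.

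The behavioural scores in the labels show how far apart the lines were. The locomotor score was 2354 ± 146 (SD, n = 6) in bHR, 491 ± 200.05 in bIR and 31 ± 9.19 in bLR, and the lines did not overlap. Each pair differed in an exact two-sided permutation test of means (adjusted p = 0.0108, from the smallest p that 6 rats against 6 allow, 0.00216). In the elevated plus maze, a test of anxiety-like behaviour, bHR rats spent 35.5 ± 17.4% of the time in the open arms and bLR rats 8.28 ± 9.61% (exact permutation test, adjusted p = 0.0162, n = 6). The bIR rats, at 16.2 ± 11.3%, differed from neither line after adjustment over 15 tests (adjusted p = 0.0722 against bHR and 0.304 against bLR, exact permutation test, n = 6). The bLR rats were immobile for longer than bHR rats (109 ± 64.4 against 31.4 ± 7.34, unit not stated) and than bIR rats (35.2 ± 1.91), with an adjusted p of 0.0162 in both exact permutation tests. Faecal boli numbered 3.00 ± 1.90 in bLR and 0.167 ± 0.408 in bIR (exact permutation test, adjusted p = 0.0325, n = 6). Distance travelled in the maze separated no pair of lines (adjusted p from 0.0568 to 1.00, exact permutation test, n = 6). The bIR rats were tested in the maze at P65 to P75 and the others at P160 to P167. The bIR rats were thus sacrificed longer after the maze than the others. In all, 7 of the 15 comparisons passed, and 6 with medians in place of means, where faecal boli no longer differed between bLR and bIR (exact permutation test, adjusted p = 0.114).

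**Figure D1:**
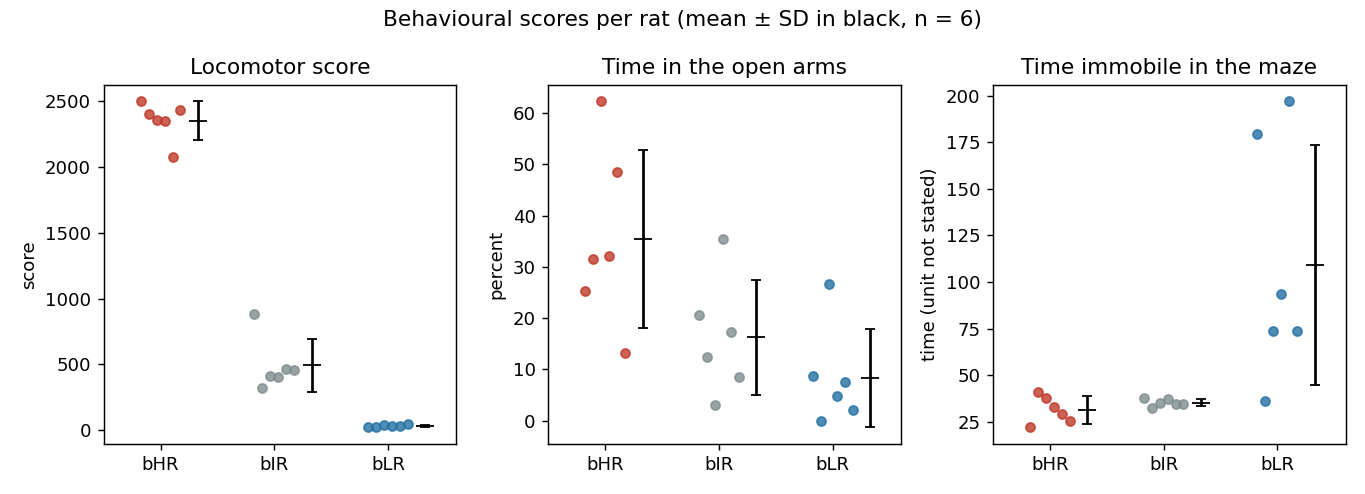
Locomotor score, percent time in the open arms and time immobile in the maze (unit not stated), each point a rat, with the mean and SD of the 6 rats of a line in black. The locomotor scores lie between 2079 and 2501 in bHR, between 323 and 886 in bIR and between 20 and 44 in bLR.

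The comparison of bHR with bLR asks which hippocampal transcripts differ between the selectively bred lines. With limma and Benjamini-Hochberg adjustment, 93 of 20909 genes differed at an adjusted p under 0.05. Of these, 40 were higher and 53 lower in bHR, 36 of them by at least 2-fold, and 73 showed no overlap between the 6 bHR and the 6 bLR rats. Over all genes, 0.909% had no overlap between these lines, where chance gives 0.216%. An unadjusted p under 0.05 was reached by 1958 genes, where chance gives 1045.

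Among the genes lower in bHR, Tnnt1, a slow skeletal muscle troponin T, stood at 1.14 ± 0.257 FPM in bHR and 11.9 ± 6.67 in bLR (SD, n = 6; 9.44-fold, limma adjusted p = 0.00316). Ghdc was 4.40-fold lower in bHR (2.13 ± 0.532 against 9.28 ± 1.62, adjusted p = 2.99e-07), and Htra4, a secreted serine protease, 3.32-fold lower (adjusted p = 0.00181). Rpl17, a large-subunit ribosomal protein gene, was 3.04-fold lower (15.3 ± 4.72 against 45.6 ± 12.6, adjusted p = 0.00296); ribosomal protein genes have processed copies elsewhere in the genome, so its level is uncertain. The kinesin Kif15, the activin-binding protein follistatin (Fst), the metal transporter Slc11a1, the axon guidance receptor Robo3, the aromatic amino acid decarboxylase Ddc, the anchoring protein Akap3, Tmem144 and the endothelin receptor Ednra were also lower in bHR, with log2 differences between -1.50 (Kif15) and -0.96 (Ednra, Tmem144). The smallest adjusted p was that of LOC102555248, a gene with a placeholder symbol that was chosen after its values were seen. It stood at 1.01 ± 0.205 FPM in bHR and 24.3 ± 3.83 in bLR (log2 difference -4.59, SE 0.14, adjusted p = 1.67e-15).

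Among the genes higher in bHR, Asb15, an ankyrin repeat protein, showed the largest log2 difference of those named by the rule, which asks for a mean log2 value of at least 0 (5.35, SE 0.96, adjusted p = 0.00916). It had 294 to 765 reads in each bHR rat and 3 to 9 reads in the bLR rats other than LR_48, which had 284. Albumin (Alb) stood at 18.1 ± 3.15 FPM in bHR and 4.52 ± 2.99 in bLR (adjusted p = 0.00174). Testin (Tes) was 1.98-fold higher in bHR (29.9 ± 3.84 against 15.2 ± 2.86, adjusted p = 2.30e-04), the peroxisomal membrane protein Pxmp4 1.91-fold higher (adjusted p = 0.00492) and the secreted calcium-binding protein Smoc1 1.90-fold higher (18.9 ± 2.49 against 9.94 ± 0.714, adjusted p = 2.30e-04). Smaller differences were found in the kinase inhibitor Pkib (log2 difference 0.68), adenylate kinase Ak1 (0.67), Ttc30a1 (0.66), Amer2 (0.65), Mcmdc2 (0.60), the metalloprotease Adamts20 (0.59) and the lysosomal membrane protein Scarb2 (0.52, adjusted p = 4.56e-04). Of 33 called genes (those named by the rule, as candidates or as list members, and LOC102555248), 15 stayed past the threshold under all alternative settings and without any single rat, among them Ghdc, Tnnt1, Htra4, Rpl17, Tmem144, Slc11a1, Alb, Tes, Smoc1, Ak1 and Scarb2. With sequencing depth as a covariate 41 genes were called, 36 of them among the 93, and the other calls were lost. Among the named genes these were Pxmp4, Pkib, Kif15, Robo3, Adamts20, Ddc, Ist1, Fxyd7, Ifit1, Ttc30a1, Fst, C1qb, Akap3, Mvb12b, Ednra and Mcmdc2 (adjusted p from 0.0514 for Pxmp4 to 0.238 for Mcmdc2). With voom weights Asb15 (adjusted p = 0.103) and Ifit1 (0.109) were not called.

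**Figure D2:**
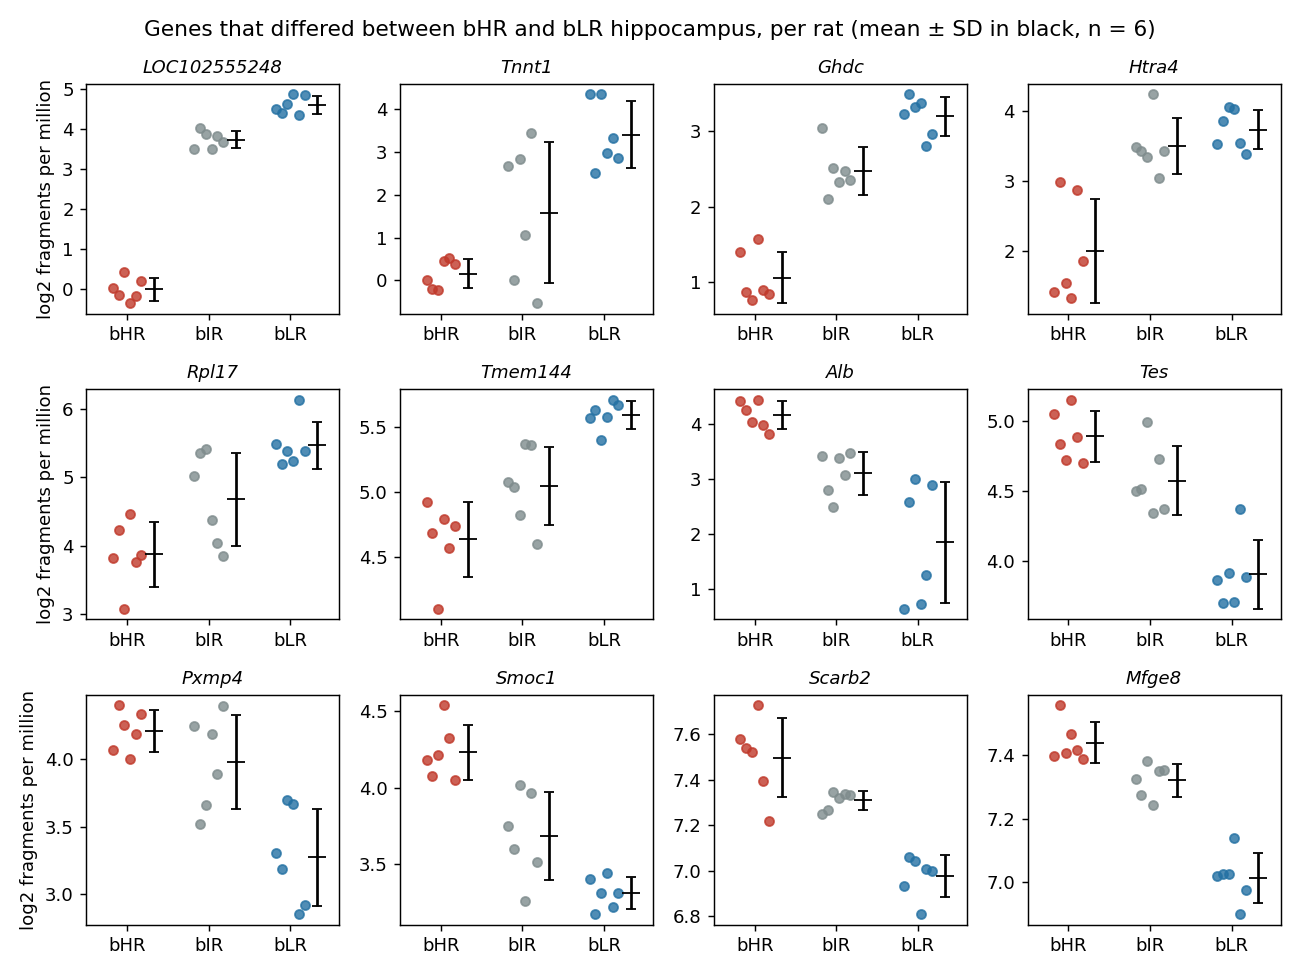
Values of 12 genes that differed between bHR and bLR, in log2 FPM, each point a rat, with the mean and SD of the 6 rats of a line in black. The bHR and bLR rats do not overlap in any of the 12 genes; Ghdc stands at 2.13 FPM in bHR, 5.65 in bIR and 9.28 in bLR.

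A list of 34 candidate genes, taken from the literature on these lines and in part on these samples, is not independent evidence. Of its 33 measured members, 3 were higher in bHR (Mfge8, Aldh1a1, Ttc30a1), 7 were lower (Tnnt1, Ghdc, Tmem144, Pex11a, Fxyd7, Ist1, Mvb12b) and 23 did not pass. Adjusted over the list alone 26 passed, a number that choosing genes in part from these samples would raise. Mfge8, a secreted bridging protein in the clearance of dying cells, was 1.34-fold higher in bHR (174 ± 7.90 against 129 ± 7.06 FPM, SD, n = 6; limma adjusted p = 2.30e-04). Aldh1a1, a retinaldehyde dehydrogenase, was 1.67-fold higher (adjusted p = 0.00523), and Pex11a, a peroxisome proliferation factor, 1.87-fold lower (adjusted p = 0.00296). The calls of Fxyd7 and Mvb12b lie close to the threshold (adjusted p = 0.0469 and 0.0480) and were kept in 5 and in 1 of the 18 fits that left out a rat. Of the other named genes, Mcmdc2 was kept in 4 of these fits, Ddc in 7 and C1qb in 9.

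Gene lists of cell types and pathways, fixed beforehand, held few genes that passed one by one. With the preset correlation of camera, 8 of 32 lists were called between bHR and bLR, and none was called with an estimated correlation (smallest adjusted p = 0.568). The astrocyte markers were higher in bHR in 13 of 14 members (median log2 difference 0.15, camera adjusted p = 1.00e-04; adjusted p = 0.568 with an estimated correlation), with 0 members called and 2 adjusted over the list alone. Gfap and Aqp4 had log2 differences of 0.33 and 0.25. The microglia markers were lower in 15 of 17 (median -0.15, adjusted p = 1.00e-04; 0.568 as the adjusted p with an estimated correlation), where C1qb, a complement component that the complement list also holds, was called (log2 difference -0.42, limma adjusted p = 0.0382) and 4 passed adjusted over the list alone. Endothelial markers were lower in 10 of 13 members (median -0.19, adjusted p = 3.63e-04; adjusted p = 0.568 with an estimated correlation), with 0 called and 4 adjusted over the list alone, and mural cell markers in 9 of 10 (median -0.20, adjusted p = 0.0210; adjusted p = 0.705 with an estimated correlation). Dentate gyrus granule cell markers were lower in 9 of 10 (median -0.27, adjusted p = 0.0140; adjusted p = 0.568 with an estimated correlation), among them C1ql2 with a log2 difference of -0.62. Genes of the major histocompatibility complex and antigen presentation were lower in 17 of 24 (median -0.14, adjusted p = 0.0126; adjusted p = 0.705 with an estimated correlation), with 0 called and 6 adjusted over the list alone; Cd74, the class II invariant chain, had a log2 difference of -0.86 and an adjusted p of 0.0861, and the RT1 genes of this list are near-identical copies, so their levels are uncertain. All 13 ependymal cilia markers were higher in bHR (median 0.26, adjusted p = 0.00140; adjusted p = 0.705 with an estimated correlation), as were 14 of 17 oligodendrocyte and myelin markers (median 0.10, adjusted p = 0.0426; adjusted p = 0.819 with an estimated correlation). The other 24 lists were not called (camera adjusted p of 0.238 or more). Members called one by one outside the 8 lists were Fst among BMP signalling genes, Pex11a among peroxisome and fatty acid oxidation genes, and Ifit1 among interferon response genes. Ifit1 had 40 to 145 reads in bHR and 0 to 5 in bLR (log2 difference 6.30, SE 1.22, adjusted p = 0.0183); with so few reads in bLR the size of this difference depends on the offset. Among lists with a called member, median and mean differed in sign for BMP signalling (0.06 and -0.03), interferon response (-0.03 and 0.30) and complement genes (-0.07 and 0.02). They also did so for the thalamus, CA1 pyramidal cell, glucocorticoid and stress axis, and monoamine lists, none of which held a called member.

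The comparisons with bIR ask where a cross of the lines lies. Against bHR, 2 genes differed with limma, both lower in bHR: LOC102555248 (log2 difference -3.74, SE 0.14, adjusted p = 1.19e-13; chosen after its values were seen) and Ghdc (log2 difference -1.41, SE 0.17, adjusted p = 4.60e-04), neither with overlap between the rats. Without the 4 libraries with Ttr above 11, a setting chosen after seeing the data, Ghdc was not called (log2 difference -1.40, adjusted p = 0.0534, the highest over the alternatives, whose lowest was 1.19e-04), and the count of 2 held 1 gene higher and 1 lower in bHR. At an unadjusted p under 0.05 there were 1214 genes, where chance gives 1045. Against bLR, 0 genes passed with limma (smallest adjusted p = 0.0670) and 1524 genes had an unadjusted p under 0.05; voom weights called 1, and both filters on low values 2. Against the mean of bHR and bLR, 1 gene passed, LOC102555248, higher in bIR by 1.44 on the log2 scale (SE 0.12, adjusted p = 1.12e-06), with 1178 genes at an unadjusted p under 0.05. In FPM, bIR stood at 13.4 ± 1.91 for this gene, against a mean of 12.7 for the lines.

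Among the 93 genes that differed between bHR and bLR, the bIR mean lay between the line means in 92. On a scale from 0 at the bLR mean to 1 at the bHR mean, the median position of bIR on log2 values was 0.481 (quartiles 0.369 and 0.612). It lay from 0 to 1 for 92 genes and above 1 for the neuropeptide cortistatin (Cort, 1.18), chosen after its values were seen. Ghdc, Tmem144, Smoc1 and Alb all had bIR means between the lines: for Smoc1, 18.9 FPM in bHR, 13.1 in bIR and 9.94 in bLR. A mean in between need not be the level of each rat. For Tnnt1, IR_149, IR_213 and IR_261 stood at 6.38, 7.14 and 10.8 FPM, within the bLR range (5.73 to 20.4). IR_158, IR_293 and IR_248 stood at 1.00, 0.692 and 2.10, near the bHR range (0.855 to 1.43). For LOC102555248 all bIR rats (11.3 to 16.1) lay between the lines. How many genes follow either pattern was not tested. A median near 0.5 also arises without any relation between the lines, since genes picked for a large difference leave an unrelated group in the middle: in 99 random splits of the bHR and bLR rats, the 93 genes of smallest p gave a median position of 0.492 and a median of 87.1% between 0 and 1, with 98.9% in the highest, which equals the 98.9% found here. The positions were less spread than in most of these splits, with an interquartile width of 0.244 against a median of 0.400, and 2 of the 99 were narrower. Since a position is divided by the difference between bHR and bLR, which is larger in the real split, neither this width nor the share between 0 and 1 shows how bIR relates to the lines.

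**Figure D3:**
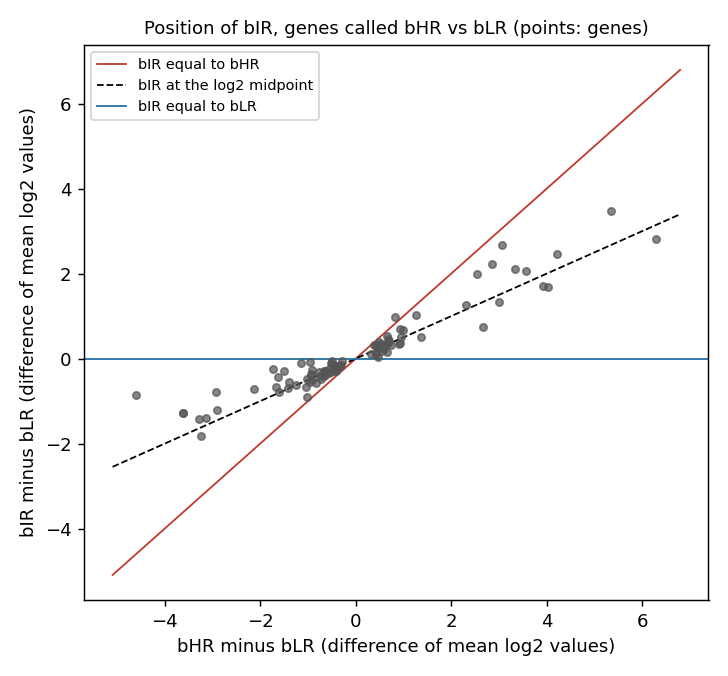
Difference of bIR from bLR (vertical) against difference of bHR from bLR (horizontal), both as differences of mean log2 values, for the 93 genes called between bHR and bLR, each point a gene. The dashed line marks the log2 midpoint, and the median position is 0.481.

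Of the gene lists, camera with the preset correlation called 9 between bHR and bIR, 11 between bLR and bIR and 7 between bIR and the mean of the lines. With an estimated correlation none was called in these contrasts (smallest adjusted p = 0.578, 0.352 and 0.177). Against bHR all 15 immediate early genes were higher in bIR (camera adjusted p = 6.99e-07; adjusted p = 0.578 with an estimated correlation), and against bLR 14 of 15 were (camera adjusted p = 1.52e-07; adjusted p = 0.352 with an estimated correlation). Endothelial markers were higher in bLR than bIR in 11 of 13 members, 5 of them adjusted over the list alone (camera adjusted p = 1.93e-05; adjusted p = 0.352 with an estimated correlation). All 15 immediate early genes, transcripts induced by neuronal activity, were higher in bIR than the mean of the lines (median log2 difference 0.33, camera adjusted p = 2.84e-10; adjusted p = 0.177 with an estimated correlation), with 0 called over all genes and 8 adjusted over the list alone. Egr2 stood at 2.33 ± 1.27 FPM in bIR, 1.06 ± 0.349 in bHR and 0.961 ± 0.298 in bLR (SD, n = 6), and Fos at 8.29 ± 4.64, 5.31 ± 1.39 and 3.32 ± 0.855. Among bIR, IR_248 and IR_149 had the highest list means (4.08 and 3.83 on the log2 scale, the other bIR rats 3.26 to 3.59), with Fos at 16.4 and 10.7 FPM. Without IR_248 the median difference of the list was 0.31. The 15 choroid plexus markers were all higher in bIR (median 1.58, adjusted p = 2.90e-07; adjusted p = 0.707 with an estimated correlation), as were the 12 meningeal fibroblast markers (median 0.59, adjusted p = 7.14e-06; adjusted p = 0.707 with an estimated correlation). These markers varied by library: transthyretin (Ttr) exceeded 11 on the log2 scale in IR_213, IR_248, IR_261 and HR_38, reaching 13406 FPM in IR_261 against 75.4 in LR_16. Without these 4 libraries the median choroid plexus difference was -0.35. Of the other lists called in this contrast, interferon response genes were higher in bIR in 17 of 20 members (adjusted p = 0.00508; 0.707 as the adjusted p with an estimated correlation), and endothelial markers (11 of 13 lower, adjusted p = 0.00554; adjusted p = 0.707 with an estimated correlation), CA2 and CA3 pyramidal cell markers (12 of 14 lower, adjusted p = 0.0460; adjusted p = 0.707 with an estimated correlation) and nuclear-encoded oxidative phosphorylation genes (30 of 35 lower, median -0.06, adjusted p = 7.97e-04; adjusted p = 0.780 with an estimated correlation) were lower. With the choroid plexus mean as a covariate, a setting chosen after seeing the data, only the immediate early gene and oxidative phosphorylation lists stayed called of those tested. The interferon response, meningeal, endothelial, and CA2 and CA3 lists were then not called, nor were they without the 4 libraries, where the interferon median was 9.69e-04.

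**Figure D4:**
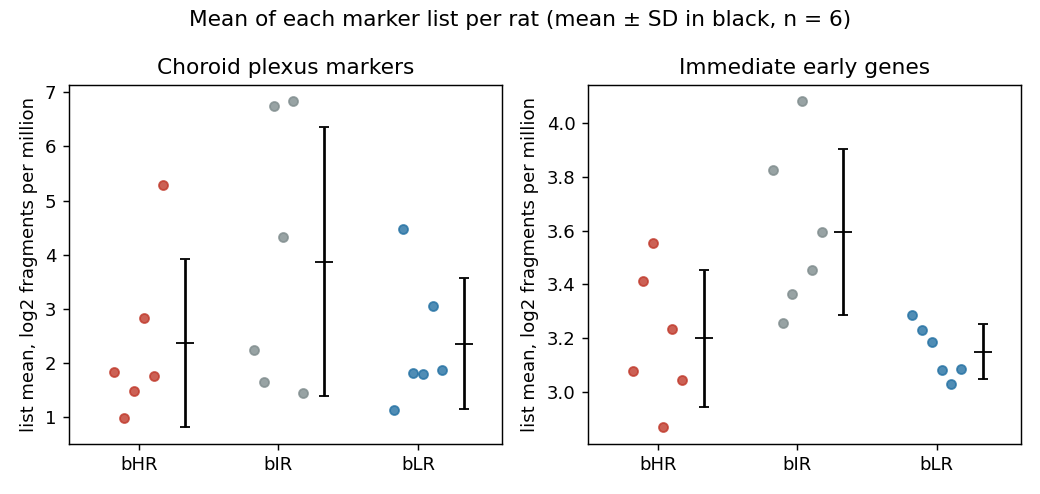
Mean of the choroid plexus markers and of the immediate early genes in each rat, in log2 FPM, each point a rat, with the mean and SD of the 6 rats of a line in black. The choroid plexus mean ranges from 0.990 in HR_22 to 6.83 in IR_261.

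Within lines, no gene passed the threshold for an association with percent time in the open arms. With a common slope in limma, 0 of 20909 genes passed (smallest adjusted p = 0.999), and 907 had an unadjusted p under 0.05 where chance gives 1045. The power of this test was not assessed, so associations are not excluded. The common slope also joins bIR scores taken long before sacrifice with scores of the other lines taken close to it.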

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

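The tests of carried-over tissue, of depth and of the line difference in choroid plexus markers were chosen after the results were seen; the splits of the rats and the comparison of ages were fixed before. In 297 groups of 6 rats (15 of behavioural scores, the others of 94 named genes), the rat farthest from the others was compared with Dixon's critical value for 6 samples. If the values of each group followed a normal distribution, about 14.9 groups would lie past it, and 25 did. Faecal boli are counts with ties, and genes of the same list can move together. Whether 25 is an excess was therefore not tested.

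Among behavioural scores, IR_158 travelled 29024 in the maze (unit not stated) where the other bIR rats lay between 2212 and 4556 (gap over range 0.913). IR_149 had a locomotor score of 886 (0.744) and HR_34 of 2079 (0.649). LR_32 spent 26.8% of the time in the open arms, the other bLR rats at most 8.60% (0.679). HR_38 left 4 boli and IR_261 left 1, with 0 in the other rats of those lines (ratio 1 in both).

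Among genes, Asb15 stood at 2.63 on the log2 scale in LR_48, the other bLR rats at most -2.33 (gap over range 0.811), and at -3.51 in IR_293, the other bIR rats at least 2.18 (0.905). LR_48 also stood apart in Rpl17 (0.686), Tes (0.679) and Fa2h (0.786). LR_48 lay nearer to the bHR mean than to that of the other bLR rats in 10 of the 93 called genes, and HR_38 nearer to bLR in 16. IR_248 was highest in C1qc (0.646), Htra4 (0.631), Egr2 (0.643) and Ndufb8 (0.757), and IR_293 in Pdgfrb (0.861). HR_26 was lowest in Cldn11 (0.697), Itm2a (0.642) and Tspan2 (0.708). Other rats standing apart were those for Mvb12b in HR_38 (0.726), Pdia5 in HR_10 (0.695) and in LR_20 (0.718), Aqp4 in LR_8 (0.678), Cd68 in LR_44 (0.676) and Col1a1 in IR_158 (0.638).

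The choroid plexus markers were high in some libraries, 3 of the 4 above the Ttr limit being bIR; this count depends on the limit, since LR_20, just under it, had a list mean of 4.48 and IR_248, above it, 4.33. Carried-over choroid plexus tissue may account for this, as the 15 markers moved together within lines (median pairwise correlation of deviations 0.951, quartiles 0.928 and 0.972), though a change within the choroid plexus of those rats would move them together too. The list mean of bIR exceeded that of the other 12 rats by 1.51 on the log2 scale, with an exact permutation p of 0.110, so a difference between the lines cannot be told apart from uneven tissue here, given 6 rats a line.

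The immediate early genes were higher in bIR than the mean of the lines by a median log2 of 0.33. Carried-over choroid plexus tissue is argued against, since the median was 0.44 with the choroid plexus mean as a covariate and the list stayed called. A difference in depth is argued against likewise, with a median of 0.30 under the depth covariate. Age stays open: 0 of the bIR rats overlapped in age at sacrifice with another line. The bIR rats, tested in the maze at P65 to P75, were also sacrificed longer after it than the others, tested at P160 to P167. Line, age, time since the maze and the day of handling therefore cannot be told apart. The list itself is not secure, with an exact permutation adjusted p of 0.0603 and an adjusted p of 0.177 with an estimated correlation.

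The 93 genes between bHR and bLR might reflect depth, since bLR libraries were deeper and 41 genes were called with depth as a covariate. Against this, the log2 differences hardly moved: the ratio of the difference with the covariate to that without had a median of 0.998 over the 93 genes (quartiles 0.923 and 1.04), and all 93 kept their sign. The SE rose by a median factor of 1.13, and 36 of the 93 genes were among the 41; why the other calls were lost was not tested. A genetic difference between the lines stays open as untested.

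Other splits of the same rats were counted, 100 per comparison with the real one included. For bHR against bLR, 1 of 100 splits, the real one, gave 93 genes, and the highest other gave 1. A chance split of these rats can thus be excluded as the source of the count. A batch or litter shared within a line, which the labels do not give, cannot be told apart from line by these splits. For bHR against bIR, 3 of 100 splits, the real one included, gave at least 2 genes. This share is under 0.05, the limit set beforehand, but the highest other gave 180, so chance is not excluded for a count of 2. A count does not weigh single genes: the limma adjusted p of LOC102555248 was at most 6.51e-09 over 32 settings. For bIR against the mean of the lines, 6 of 100 splits gave at least 1 gene, the highest other 133, so chance cannot be excluded for that count. The 0 genes between bLR and bIR were reached by 100 of 100 splits, the highest other giving 2. Any split reaches a count of 0, so this says nothing about chance. The splits with 180 and 133 genes may reflect a structure of the samples, which was not tested. By size of the choroid plexus difference these splits ranked 96 and 30 of 100. For list counts chance cannot be excluded: as many lists were called in 19 of 100 splits for bHR against bLR (8 real, highest other 13), in 25 for bHR against bIR (9 real, 16), in 13 for bLR against bIR (11 real, 14) and in 41 for bIR against the mean of the lines (7 real, 13).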

How the results depend on the processing

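The covariate of choroid plexus markers, the fits without the 4 libraries with Ttr above 11, the exact permutation of list means, and some settings carried over to the lists and the bIR position were chosen after seeing the data. Between bHR and bLR, 93 genes were called, 194 with array weights and 41 with the depth covariate. Leaving out 1 rat gave 46 to 138 genes, with counts more than 1.5 times lower without LR_8 (46), HR_10 (52), HR_34 (53), LR_44 (57) or LR_20 (59). None of the 93 genes reversed in any setting that tested it. Between bHR and bIR, 2 genes became 6 with array weights and 3 with the depth covariate. Without the 4 libraries the count of 2 held 1 gene higher and 1 lower in bHR, where both were lower with all libraries. Ghdc was then no longer called (limma adjusted p = 0.0534). Leaving out 1 rat gave 2 to 4 genes (4 without HR_34 or HR_38, and 3 without HR_22, HR_26, HR_2, IR_149 or LR_48). Between bLR and bIR, 0 became 2 with either filter on low values, 1 with median centring, 3 with array weights, 1 with voom weights, 1 with only the bLR and bIR rats, and 0 to 2 without 1 rat (2 without HR_26, IR_158, LR_16 or LR_48; 1 without HR_2). For bIR against the mean of the lines, 1 gene was called in every setting and without any rat. The open arm slope gave 0 throughout. The bIR position was 0.426 to 0.524 over the settings and 0.449 to 0.532 without 1 rat. The number of lists fell to 0 with an estimated correlation and to 0 with the permutation in all 4 contrasts, where the smallest adjusted p of the permutation ranged from 0.0603 to 0.673; between 2 lines, 1 list alone could not go below 0.0693, so its fall to 0 there says little. With the choroid plexus covariate 4 lists were called between bHR and bIR (9 without it) and 2 for bIR against the mean of the lines (7 without). Without 1 rat the lists numbered 5 to 8 between bHR and bLR (5 without HR_2 or LR_20), 6 to 11 between bHR and bIR, 7 to 12 between bLR and bIR (7 without IR_248 or IR_293) and 4 to 10 for bIR against the mean of the lines (4 without IR_248). The cause was not tested.

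Without the 4 libraries, directions reversed for choroid plexus markers (median 0.0576 for bHR minus bIR, 0.59 for bLR minus bIR, -0.35 for bIR minus the mean of the lines), as leaving out libraries rich in that list must favour, and for Prlr (0.0321 for bLR minus bIR), Bst2 (-0.0249), Ifi44 (-0.0572; both bIR minus the mean of the lines) and the interferon response list (direction of the camera test; median -0.00235 for bHR minus bIR, still negative). The choroid plexus list was not tested with its own mean as a covariate. Of the behavioural comparisons 7 passed, 6 with medians. Distance in the maze reversed for bHR minus bIR, to 2026 with medians and 1506 without IR_158, and for bLR minus bIR, to 6.96 with medians. Other named genes kept their direction in the settings run. No paired analysis was possible because the lines share no replicate numbers.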

Other observations

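The neighbour test was fixed before its result was seen; the linear scale test was chosen after. Several marker lists were not called between bHR and bLR: thalamus markers had a median log2 difference of -0.07 (mean 0.01, camera adjusted p = 0.808) and neocortex markers of 0.12 (adjusted p = 0.864). Interneuron markers (11 of 16 higher, adjusted p = 0.248), cell cycle genes (11 of 17 higher, adjusted p = 0.819), neurogenesis genes (9 of 15 higher, adjusted p = 0.377) and FGF signalling genes (8 of 16 higher, adjusted p = 0.913) were not called either, nor were glucocorticoid and stress axis genes (adjusted p = 0.909).

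A first hypothesis was that genes called between bHR and bLR lie next to one another, as blocks of linked variants in bred lines may produce. By gene order in GRCr8, 76 of the 93 genes could be placed among 16221 measured genes. Of these, 12 had another called gene within 10 measured genes, where random draws matched on expression gave a median of 6 (permutation p = 0.0905 over 10000 draws), which leaves clustering undecided. The 6 pairs were Syt5 with Tnnt1, Mfge8 with Pex11a, Ifit1 with Pank1, Rassf6 with Alb, Htra4 with Adam32 and Kif15 with Limd1, named after their values were seen, and 2 of them held 1 gene in each direction.

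A second hypothesis was that LOC102555248, the gene off the mean of the lines on the log2 scale, lies midway on the linear scale. bIR differed from the mean of the lines by 0.737 FPM (interval of 2 SE from -1.47 to 2.95), against 24.3 in bLR and 1.01 in bHR. This is consistent with a midway level, as a cross carrying 1 copy from each line could give; the log2 call then follows from the scale. Ifit1 varied within bIR, with 61, 159 and 56 reads in IR_149, IR_248 and IR_293 and 0 or 1 in the other bIR rats.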
